A study of Schistosoma mansoni with 4 samples.

How the data were processed

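RNA of microdissected oesophageal gland and of microdissected whole male worms was measured on 4 arrays, in 2 groups of 2, grouped by the tissue given in the labels. Per the labels' protocols, total RNA was isolated with a kit for small samples, and Cy3-labelled cRNA was made from 20 ng by linear amplification. Per the file headers, each array was read with Agilent Feature Extraction 10.1.1.1, whereas the submitters' processing notes name version 9.1. Each scanner file holds 43426 spots, 42009 of them non-control, for 41739 probes, of which 30 had more than 1 spot (up to 10). Per the file headers, the processed spot intensity is background-subtracted and spatially detrended within an array, and it is not normalized between arrays. The median spot and background intensity deposited by the authors is raw pixel brightness. Depth is given by the share of spots well above background, from 46.4% to 56.6% per array, and by the 75th percentile of intensity (91.3, 107, 206 and 184 on gland arrays 1 and 2 and whole-male arrays 1 and 2). Of non-control spots, 2 were saturated on gland array 1 and 0 on each of the others.

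The authors' deposited table gives, per its header, an unadjusted p-value of an unpaired t-test for probes called present or marginal. It also gives the authors' raw group mean intensity, their normalized group means on a log2 scale, centred per probe, and a fold that equals the ratio of the raw means. The percentile of their scaling is not given in the sources used here. The table and short list pair probes with genome predictions, scaffold positions and BLAST descriptions. No assembly version is given for these positions, and the header warns that some probes lie on the strand opposite to the prediction. The table's 4 per-array detection columns were not used.

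The log2 processed intensity minus each array's 75th percentile over non-control spots was the value compared. Outlier spots were left out (22, 19, 19 and 36 in the same order), saturated spots were kept and spots of a probe were averaged. Probes well above background on both arrays of at least 1 group were tested, 21838 in all, with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with group as the only term and 2 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. For a probe not well above background on either array of a group, the fold is a bound: the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

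A gene was the table's genome prediction, or the leading BLAST description where there was none. Names come from the deposited table and are those of the array's design, and many are BLAST matches to other organisms. Of 2622 predictions, 2141 were found in the RefSeq gene table of assembly ASM23792v2, from which no coordinate was used. Of the table's 5740 probes, 4817 had a name. When lists were first built, descriptions such as "unknown" had counted as names, which merged unrelated probes into 1 gene and put that gene in several lists. After the list results had been seen, probes with only such descriptions were treated as unnamed, and where the leading description was of this kind the whole text was used. This raised the named genes from 3311 to 3332 and the called lists from 8 to 9 by adding tegument genes, and changed the largest named decreases. The first build is kept as an alternative. Of 798 genes with more than 1 probe, 572 had more than 1 called probe, and 20 of them had calls in both directions.

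Before the data were examined, 24 gene lists were fixed as keyword patterns, among them markers of other tissues: gut, tegument, muscle, male reproductive organs, vitelline cells, neurons, parenchyma and dividing cells. Patterns were searched in product and BLAST descriptions, so a list holds some genes that match by a word only. Only the authors' deposited table gives these descriptions, so array probes outside it could not enter a list. The brightest probe stood for each gene. Lists of at least 5 members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists tested. Members were counted at the threshold adjusted over all probes and adjusted over the list alone.

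The rule for named genes was also fixed before the data were examined. It took the 12 largest increases and 12 largest decreases among named probes past the threshold with both gland arrays beyond both control arrays, 1 per gene. It added every micro-exon and venom allergen-like member, and the 2 largest increases and 2 largest decreases in each other list. At most 2 unnamed probes that rose and 2 that fell could be given. It named 104 probes.

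Alternatives covered background correction, scaling, filters, the variance model, the test, a replicate block, each array left out, and the way lists were built and tested. The filter settings and the intensity trend gave camera the same values for list genes, so in list tallies they repeat the reported outcome. The methods' t-test was run on the same values at its own threshold and after Benjamini-Hochberg adjustment. Spike-in scaling used 8 spike-in probes above the detection limit on every array.

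The fit was tested on simulated data with the real mean levels of the 21838 probes. Each probe's variance was drawn from limma's fitted prior distribution and was the same on all 4 arrays. With 50 probes changed per size, it recovered 0% at a log2 change of 0.5, 4% at 1, 46% at 2 and 90% at 4, and called 7 unchanged probes. With 6076 probes changed by the observed sizes, it recovered 76.9%, and 3.51% of its calls were false. In the data the gland arrays differed more from each other (SD of the log2 difference 0.565) than the whole-male arrays (0.229). These rates may therefore not carry over to the data. Among 3332 simulated genes in 21 lists, camera gave the shifted list an adjusted p of 3.87e-52 and called 0 of the unshifted lists. Genes varied independently in this simulation, so it could not show false calls from correlated genes. No gene outside the shifted list changed, whereas in the data 1021 of 3332 named genes rose and 1222 fell. The simulation therefore does not show how camera does against such a background. Estimated correlations in the real lists reached 0.178.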

Results

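Transcript levels were measured in the oesophageal gland of adult male Schistosoma mansoni, a blood-dwelling flatworm, and in whole male worms. The gland surrounds the oesophagus and secretes into its lumen, where ingested blood passes on its way to the gut. The gland samples and the whole-male controls were both collected by laser microdissection. Each of 4 samples, 2 per group, was labelled with Cy3 from 20 ng of RNA and hybridised to its own single-colour Agilent array of 41739 probes. The labels do not say whether replicates came from separate worms or pools, so p-values measure only the spread between these samples, which may be technical. All 4 arrays lay on 1 slide, and array position on it cannot be told apart from group.

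Spots well above background made up 46.4% and 48.3% of the 42009 non-control spots on gland arrays 1 and 2. The whole-male arrays 1 and 2 had 56.6% and 52.4%. Total processed signal was 1.89e+07 and 2.0e+07 on the gland arrays against 3.25e+07 and 3.05e+07 on the whole-male arrays. The 100 brightest spots held 36.5% and 30.1% of the signal on the gland arrays and 20.5% and 20.7% on the whole-male arrays. Across the 21838 probes tested, Pearson's r of log2 values was 0.977 between the gland arrays and 0.996 between the whole-male arrays. Between groups r ran from 0.910 to 0.917. These correlations are across probes, which are not independent replicates. The number of arrays limits the precision.

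The series addresses which transcripts the gland carries at higher or lower levels than the whole male worm. The largest named increases in the gland were a tyrosinase, eggshell and female-specific proteins, a superoxide dismutase and proteins of undescribed function. Tyrosinase 2 precursor (Smp_013540), of a family of enzymes that cross-link eggshell, was 91.4-fold higher. At its most changed probe, a Pro-His-rich protein (Smp_000420) was 69.6-fold higher. The superoxide dismutase precursor (Smp_095980), which removes superoxide, was 65.8-fold higher at its most changed probe. The largest named decreases included 3 cysteine proteases of the C1 family, whose relatives digest blood proteins in the gut. Among them, Smp_139240 was 26.6-fold lower in the gland, with 4.03 ± 0.06 on the whole-male arrays against -0.70 ± 0.36 on the gland arrays (log2 signal over the array's 75th percentile, mean ± SD, n = 2 each).

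Of the 21838 probes tested with limma, 2657 were higher in the gland and 3419 lower at the adjusted threshold, and 1534 and 2352 of these differed at least 2-fold. At an unadjusted p under the same threshold, 4251 were higher and 4864 lower. Scaled to the spike-in probes in place of the 75th percentile, 333 were higher and 6075 lower, and with no scaling 609 and 15268, so that the share of calls that were higher moved from 43.7% to 5.20% and 3.84%. The median log2 difference of all probes moved from -0.02 to -1.02 and -0.999 with these scalings, so each direction given here is relative to the bulk of transcripts on its array. Without gland array 1 or 2 the counts were 5796 and 5099 higher and 6446 and 5852 lower, and without whole-male array 1 or 2 they were 705 and 634 higher and 1250 and 1083 lower.

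**Figure D1:**
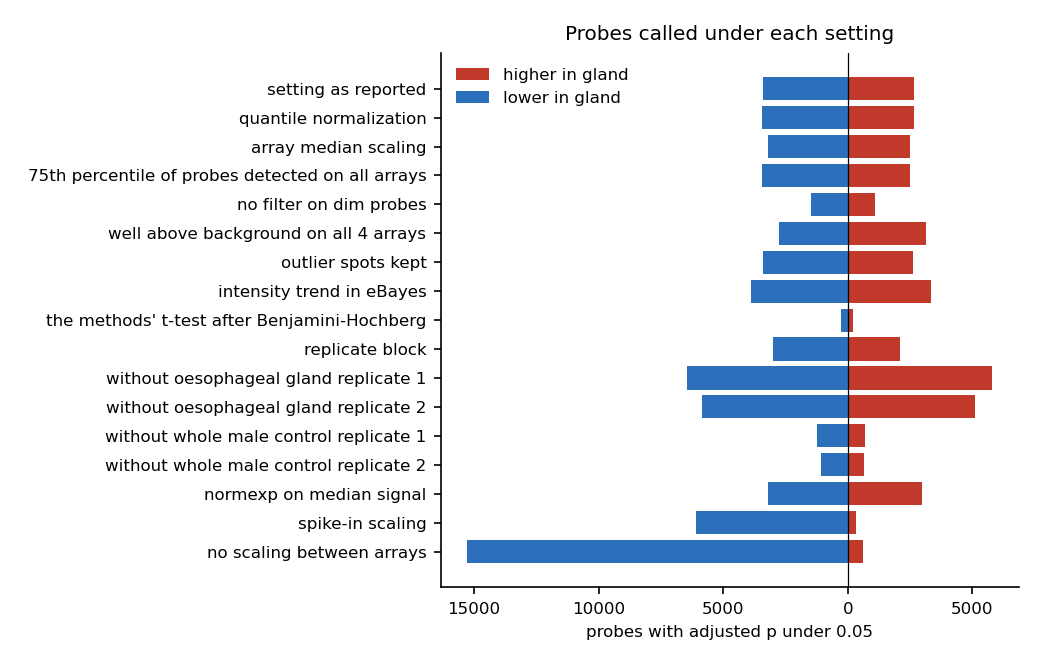
Bars give the number of probes with an adjusted p under 0.05 (horizontal axis), higher in the gland to the right of 0 and lower to the left, under each setting (vertical axis). The setting as reported gives 2657 and 3419, and spike-in scaling 333 and 6075.

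The 12 largest named increases ran from 5.82 to 6.51 on the log2 scale, each with both gland arrays above both whole-male arrays. Tyrosinase 2 precursor, on scaffold Smp_scaff000022 from 1784567 to 1788711, differed by 6.51 ± 0.26 (log2 difference ± SE, n = 2 per group, limma adjusted p = 0.000548). Its whole-male signal lay near the lowest counted as well above background. The Pro-His-rich protein, on scaffold Smp_scaff000001 from 1683593 to 1684501, differed by 6.12 ± 0.15 at its most changed probe (adjusted p = 0.000406). All 8 of its 8 probes rose, the least by 2.16. Smp_131110, whose BLAST description is an eggshell protein precursor, differed by 6.09 ± 0.32 at its most changed probe (adjusted p = 0.000955), and all 30 of its probes rose. The superoxide dismutase precursor differed by 6.04 ± 0.16 (adjusted p = 0.000406), and 3 of the 3 probes linked to that prediction rose. Probe Q2_P27243, linked to no prediction, shares the extracellular superoxide dismutase description of one of them, and fell by 3.04 (adjusted p = 0.00241). Smp_000280, described as similar to the female-specific protein FS800, rose by 5.99, the eggshell protein Smp_191910 by 5.96 and a probe described as an eggshell (chorion) protein precursor by 6.02. The remaining increases belonged to Smp_033250 (6.11), Smp_000410 (6.11) and Smp_151160 (5.82), which are hypothetical proteins, and to probes described as the SJCHGC01837 protein (6.03) and the SJCHGC09234 protein (5.96). The other probe of Smp_000410 rose by only 1.39.

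The 12 largest named decreases ran from -5.19 to -4.04. A probe described as the SJCHGC09492 protein differed by -5.19 ± 0.15 (limma adjusted p = 0.000406, n = 2 per group) and one described as the SJCHGC00969 protein by -4.95 ± 0.15 (adjusted p = 0.000406). The phospholipase D-related Smp_160830, on scaffold Smp_scaff000244 from 195129 to 218476, differed by -4.87 ± 0.19 (adjusted p = 0.000539). The C1 cysteine proteases were Smp_139240 (-4.74), Smp_187140 (-4.42) and Smp_139160 (-4.04), the last pair with cathepsin L descriptions. SJCHGC09294, at -4.68, carries the description of cathepsin A, a lysosomal carboxypeptidase. Smp_174510, a dynein light chain, stood at -4.48. The others were SJCHGC05755 (-4.69), Smp_130100 (-4.56), Smp_181070 (-4.54) and Smp_074430 (-4.32), none with a described function.

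**Figure D2:**
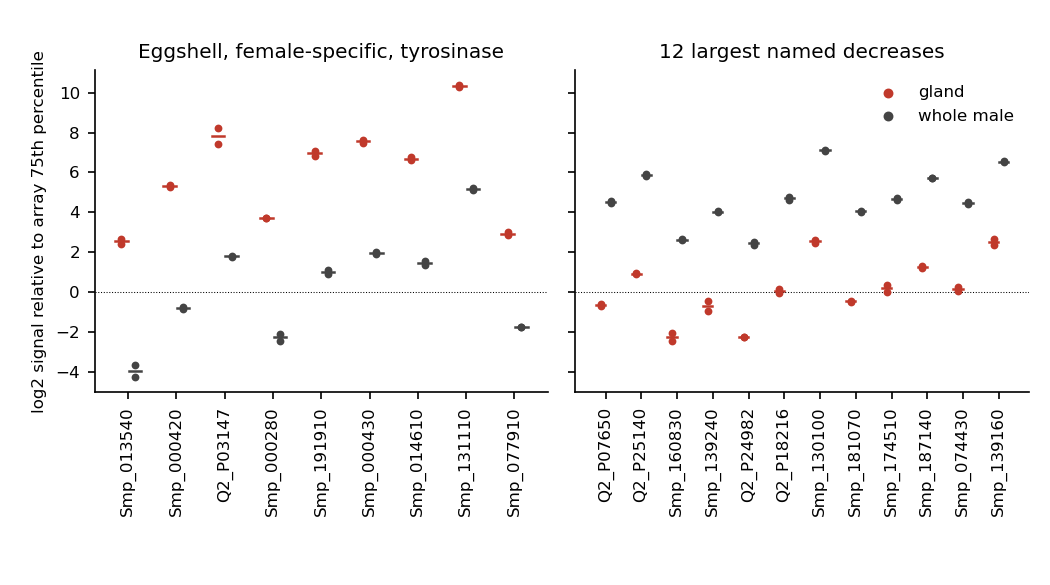
Points give each array's log2 signal relative to its 75th percentile (vertical axis) for the 9 eggshell, female-specific, Pro-His-rich and tyrosinase members of the vitelline list and for the 12 largest named decreases, with bars at the mean of the 2 arrays. The gland arrays lie above the whole-male arrays for every gene on the left and below them for every gene on the right, and each list member is drawn by its brightest probe.

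Vitelline and eggshell proteins, products of the female's yolk-forming cells, were a list fixed to reveal RNA of female tissue. Its 21 members came only from genes named in the authors' deposited table, selected on these same samples. Of these members 10 rose, 7 fell and 4 did not pass, and adjusted over the list alone 10 rose and 10 fell. The list split in 2 parts, a division made after the values were seen. The 9 members named for eggshell, female-specific, Pro-His-rich or tyrosinase proteins rose by 4.69 to 6.51, with a median of 5.96. The other 12 ran from -1.56 to 0.75, with 7 lower, among them apoferritin-2 (Smp_063530), an iron-storage protein, at -1.47. The lowest, SJCHGC07448 (-1.56), matched by a word in the description of a bestrophin channel. The list's median was -0.15 while its mean was 2.02 and its camera direction was up, and it was not called (adjusted p = 0.333; 0.518 with an estimated correlation; 1.16e-10 to 0.518 over 20 camera alternatives). Of those alternatives 7 called it, among them spike-in scaling (adjusted p = 1.16e-10), all probes (6.61e-09) and the product description alone (0.0452, with 4 of 5 members higher).

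The gene lists described next, like the vitelline list, were restricted to genes that the authors' deposited table had selected on these same samples. Their counts are therefore not independent evidence of direction. Of 22 lists large enough to test, camera called 9, with 2 higher and 7 lower, among 3332 named genes of which 1021 rose and 1222 fell. The median log2 difference of these named genes was -0.27. With an estimated correlation in place of the preset 0.01, camera called 0, and 0 also at an unadjusted p under the threshold. Parenchyma and tegument lost their calls too, though their estimates (0.0052 and 0.0058) lay below the preset. With an estimated correlation camera tests on the residual degrees of freedom, 2 here, which leaves little power. By fry, which does not compare a list with other genes and is left out of the ranges given for each list, 18 were called. As list genes were selected for a difference on these same samples, fry's calls were favoured in advance.

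Secretory pathway genes, which carry proteins through the endoplasmic reticulum and Golgi to release, were called higher by camera. Of 85 members 55 rose, 7 fell and 23 did not pass, and adjusted over the list alone 68 rose and 8 fell. The median log2 difference was 0.74 (camera adjusted p = 2.81e-07; adjusted p = 0.507 with an estimated correlation; 1.23e-07 to 0.507 over 20 camera alternatives). Smp_149610, with a mucin-like description, rose by 5.08, and the coated-vesicle cargo receptor P24 (Smp_140180) by 2.62. Smp_162770, with another mucin description, stood at -2.83 and a calcium ATPase, which pumps calcium into the endoplasmic reticulum, at -1.65. Under spike-in scaling the list's median turned to -0.26, and camera still called the list higher (adjusted p = 0.000193). With either scaling the list's median lay 1.01 above that of all named genes, a gap that a constant shift per array cannot change. The 9 eggshell, female-specific, Pro-His-rich and tyrosinase members, set apart after their values were seen, moved in the same direction on these arrays.

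Proteasome and ubiquitin genes, which mark and degrade proteins, were called higher by camera, though most members did not pass. Of 49 members 14 rose, 4 fell and 31 did not pass, and adjusted over the list alone 22 rose and 5 fell. Among all 3332 named genes 1021 rose and 1222 fell, so by counts the list stood out by few falls, not by many rises. The median was 0.40 (camera adjusted p = 0.0427; adjusted p = 0.507 with an estimated correlation; 0.00655 to 0.507 over 20 camera alternatives), and -0.60 under spike-in scaling, where the call was lost (adjusted p = 0.191). With either scaling the median lay 0.67 above that of all named genes, a gap that a constant shift per array cannot change. Under spike-in scaling 0 members were higher and 8 lower. A ubiquitin conjugating enzyme (Smp_029940) rose by 1.58 and the ligase BRE1 (Smp_061480), which ubiquitinates histones, by 1.18. Ubiquitin specific protease 9 (Smp_153690) stood at -1.25 and mind bomb (Smp_171450), a ligase of Notch signalling, at -1.11. The call was also lost without gland array 1, gland array 2 or whole-male array 1 (adjusted p = 0.158, 0.188 and 0.0525).

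Gut digestive proteases were lower in the gland. Of 24 members 19 were lower, 3 higher and 2 did not pass, and adjusted over the list alone 20 were lower and 3 higher. The median was -2.86 (camera adjusted p = 0.000874; adjusted p = 0.507 with an estimated correlation; 8.48e-10 to 0.507 over 20 camera alternatives). Smp_139240 and the cathepsin A-like SJCHGC09294 stood at -4.74 and -4.68. Against them, an aspartyl protease (Smp_132480) rose by 5.11 ± 0.20 (limma adjusted p = 0.000533, n = 2 per group) and an aspartic proteinase-related gene (Smp_136720) by 3.76 ± 0.14 (adjusted p = 0.000521). Aspartic proteases cut protein chains under acid conditions. Matched on the product description alone, 12 members remained, 9 lower and 3 higher, with a median of -1.23, and the list was not called (adjusted p = 0.12).

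Muscle genes were lower in the gland. Of 75 members 52 fell, 12 rose and 11 did not pass, and adjusted over the list alone 54 fell and 15 rose. The median was -1.31 (camera adjusted p = 0.00263; adjusted p = 0.507 with an estimated correlation; 5.96e-09 to 0.507 over 20 camera alternatives). A myosin heavy chain (Smp_127460), the motor of the thick filament, fell by 2.73 and nebulin (Smp_151490) by 2.53. Gelsolin (Smp_008650), which severs actin filaments, rose by 1.60 and a paramyosin (Smp_129550) by 1.53. With the mean of all linked probes the list was not called (adjusted p = 0.0588).

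Parenchyma and extracellular matrix genes were lower, with 34 of 45 members fallen, 5 risen and 6 that did not pass. Adjusted over the list alone 35 fell and 9 rose. The median was -1.13 (camera adjusted p = 0.00456; adjusted p = 0.507 with an estimated correlation; 0.00129 to 0.507 over 20 camera alternatives). A cadherin-related gene (Smp_151620), of a cell adhesion family, fell by 2.72 and collagen alpha-1(I) (Smp_135560), a fibrous matrix protein, by 2.14. A cerebellin-related gene (Smp_105050) rose by 1.88 and nude (Smp_169560), a partner of the dynein regulator Lis1, by 0.87. The latter stood at -0.14 under spike-in scaling and at -0.12 with no scaling.

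Stem cell and DNA replication genes were lower, with 21 of 35 members fallen, 4 risen and 10 that did not pass. Adjusted over the list alone 24 fell and 5 rose. The median was -0.87 (camera adjusted p = 0.00358; adjusted p = 0.507 with an estimated correlation; 0.00332 to 0.507 over 20 camera alternatives). A nanos-domain gene (Smp_055740), of a family that maintains germ cells, fell by 3.16 and cyclin B (Smp_082490), which drives entry into mitosis, by 2.82. A histone methyltransferase (Smp_150850) rose by 1.73 and a topoisomerase (Smp_169790) by 1.71.

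Mitochondrial respiration genes were called lower by camera, though most members did not pass: of 35, 15 fell, 1 rose and 19 did not pass. Adjusted over the list alone 25 fell and 1 rose. The median was -0.53 (camera adjusted p = 0.00335; adjusted p = 0.507 with an estimated correlation; 0.000265 to 0.507 over 20 camera alternatives). Relative to the median of all named genes it stood at -0.26. Cytochrome b5 (Smp_127160), an electron carrier, fell by 1.55 and an NADH-ubiquinone oxidoreductase (Smp_038870) by 1.15. The 42 kD subunit of that complex (Smp_031710) rose by 0.67, and stood at -0.33 under spike-in scaling. An ATP synthase gamma-related gene (Smp_072350) differed by 0.37 ± 0.15 and did not pass (limma adjusted p = 0.134, n = 2 per group), and stood at -0.64 under spike-in scaling (probe Q2_P20106).

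Glycolysis genes were lower, with 11 of 15 members fallen, 1 risen and 3 that did not pass. Adjusted over the list alone 12 fell and 1 rose. The median was -0.82 (camera adjusted p = 0.014; adjusted p = 0.507 with an estimated correlation; 0.000265 to 0.507 over 20 camera alternatives). Lactate dehydrogenase (Smp_033040), which reduces pyruvate to lactate, fell by 1.86 and hexokinase, the first enzyme of the pathway, by 1.28. A 6-phosphofructokinase (Smp_043670) rose by 0.74 and stood at -0.27 under spike-in scaling. Without gland array 1 or 2, neither glycolysis (adjusted p = 0.123 and 0.0813) nor mitochondrial respiration (0.155 and 0.153) was called. Spike-in scaling called neither (adjusted p = 0.111 and 0.174), and glycolysis was also lost on the product description alone (0.26) and with the mean of linked probes (0.212). In all, 12 of 20 camera alternatives called glycolysis and 14 of 20 mitochondrial respiration. Each tally includes the filter and trend settings, which could only repeat the call.

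Tegument genes, products of the worm's body surface, were lower by a call close to the threshold. Of 46 members 27 fell, 10 rose and 9 did not pass, and adjusted over the list alone 31 fell and 12 rose. The median was -0.98 (camera adjusted p = 0.0455; adjusted p = 0.507 with an estimated correlation; 0.0182 to 0.507 over 20 camera alternatives). Smp_169200, with a Sm20.8 tegumental description, fell by 2.35 and tetraspanin 18 (Smp_152050) by 2.22, while tetraspanin D76 (Smp_041460) rose by 4.29 and an annexin (SJCHGC06871) by 4.01. The call depended on how genes were named, a rule corrected after the list results had been seen: with the first names the adjusted p was 0.0647. It was also lost without any single array, with an adjusted p of 0.275 and 0.22 without gland array 1 or 2 and 0.0525 and 0.052 without whole-male array 1 or 2. Spike-in scaling (adjusted p = 0.298), the product description alone (0.458) and the mean of linked probes (0.0588) lost it too, and 8 of 20 camera alternatives kept it. Those 8 include the filter and trend settings, which could only repeat the call.

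**Figure D3:**
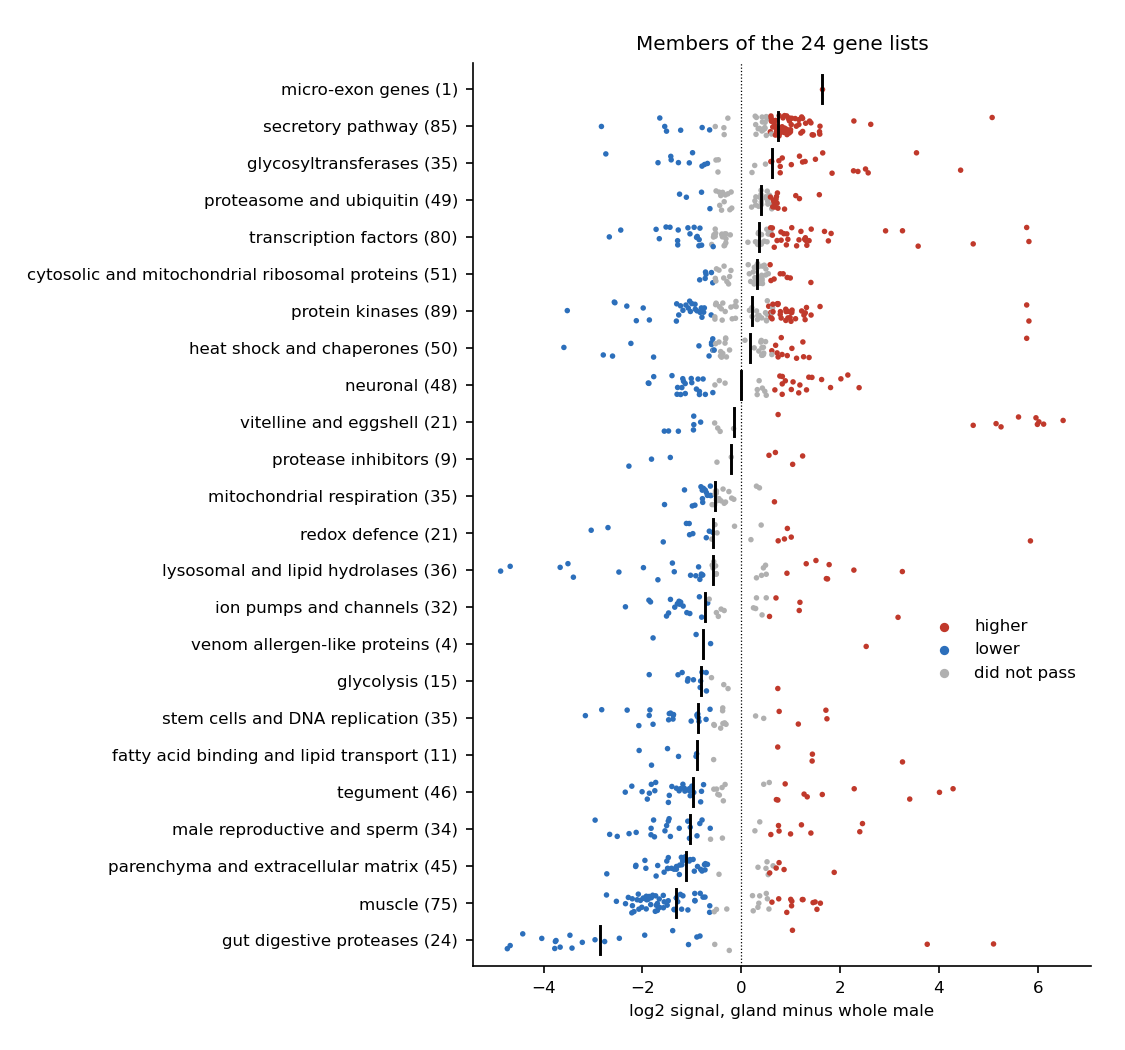
Each point is 1 member of a gene list, placed by its log2 difference between gland and whole male (horizontal axis), coloured by whether it passed the test, with a bar at each list's median and the number of members in brackets (vertical axis). Gut digestive proteases have the lowest median as drawn (-2.86; -1.23 on the product description alone) and secretory pathway genes the highest among lists of 5 or more (0.74), which turns to -0.26 under spike-in scaling. On the product description alone muscle lay lower (-1.29), and the vitelline (5.96) and glycosyltransferase (0.83) lists lay above secretory genes (0.71).

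Micro-exon genes encode secreted proteins built from very short exons, and venom allergen-like proteins are a secreted family. Both lists had too few members to test among genes named in the authors' deposited table. Other probes of the array had no names here, so it may hold further members. The 1 micro-exon entry named there, the antigen 10.3 precursor, rose by 1.63 ± 0.27 (limma adjusted p = 0.0142, n = 2 per group). Its signal went from 7.60 ± 0.02 on the whole-male arrays to 9.24 ± 0.50 on the gland arrays (log2 signal over the 75th percentile, mean ± SD, n = 2 each). Under spike-in scaling the antigen 10.3 precursor stood at 0.63 and was not called. Of 4 venom allergen-like members, VAL 13 (Smp_124060) rose by 2.53 ± 0.16 (adjusted p = 0.0015), on scaffold Smp_scaff000005 from 1921844 to 1948559. VAL 6 (Smp_124050) fell by 0.91, VAL 8 (Smp_123550) by 0.62 and a probe described as SJCHGC06310, an SCP-like extracellular protein, by 1.79. VAL 6 carries that last description too, so the 4 members may not be distinct genes. Adjusted over the list alone, 1 rose and 3 fell.

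Some probes were measured in a single group. On both gland arrays and no whole-male array, 126 probes lay well above background, of which 125 were called. On both whole-male arrays and no gland array there were 1844, of which 893 were called. Probe Q2_P23716, for which the table gives no name, was at least 257-fold higher in the gland (limma adjusted p = 0.000406), and Q2_P13217 at least 144-fold higher (adjusted p = 0.0018). Probes Q2_P01903 and Q2_P37870 were at least 37.4-fold and 30.0-fold lower (adjusted p = 0.000406 for each). All 4 were not well above background on either array of the dim group.

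The authors' deposited table lists 5740 probes at an unadjusted p of their unpaired test, the highest being 0.05. Of these, 4148 (72.3%) were also called by limma on the same arrays, which is not independent evidence. The sign of the table's normalized group means matched for all 5740 probes. The table's fold column is a ratio of unnormalized means, and its sign matched for 4010 (69.9%): it puts 1174 probes higher in the gland, where the normalized means put 2904. A deposited short list holds 286 probes with a fold of 2.00 to 46.3 by that column, and all 286 were called higher, at 1.92 to 6.51 (median 2.93) on the log2 scale. A further 1928 called probes lay outside the table, 596 higher and 1332 lower, and 1329 of them were not well above background on all 4 arrays.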

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

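Normexp on the median signal, spike-in scaling, no scaling, the product-only and linked-probe lists and the first gene names were alternatives chosen after seeing the data, and the cause of a change was not tested unless stated. Probes higher and lower in the gland, 2657 and 3419, became 1081 and 1493 with no filter on dim probes (1493 lower at least 2-fold), where 41683 probes were tested. They became 210 and 285 by the methods' t-test after Benjamini-Hochberg (151 and 228 at least 2-fold), against 3097 and 3669 at its own threshold. Spike-in scaling gave 333 and 6075, all at least 2-fold, and no scaling 609 and 15268 (447 and 10829 at least 2-fold). With spike-in scaling limma gave every probe the same SE (0.58), so these calls followed the size of the difference alone. At least 2-fold, normexp on the median signal gave 586 higher and 943 lower, and a filter of well above background on all 4 arrays gave 1442 lower, since fewer probes dim in the gland were tested. With 1 array left out the lone array is assumed to vary like the other group, and counts ran from 634 to 5796 higher, 1083 to 6446 lower, 634 to 1902 higher at least 2-fold and 1083 to 3249 lower at least 2-fold. The low ends came without whole-male array 2 and the high ends without gland array 1. Of the authors' deposited 5740 probes, 4148 were called, and 1535 with no filter, 438 by the methods' t-test after Benjamini-Hochberg, 2655 with spike-in scaling and 1049 to 5038 with 1 array left out.

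Gene lists called, 9, became 0 with an estimated correlation (0 also at an unadjusted p under the threshold) and 18 by fry, which does not compare a list with other genes, and ran from 7 to 9 with 1 array left out. The calls by fry were favoured in advance, as list genes were selected for a difference on these samples. The first gene names gave 8, all probes 13, the product description alone 10 and the mean of linked probes 6. Over 22 lists and 21 alternatives, 377 of 462 outcomes kept direction and side of the threshold, 42 lost a call, 37 gained one and 6 reversed camera's direction, none called in either setting. These were protease inhibitors (median 0.43 with all probes, 0.56 on the product description and 0.091 with linked probes), neuronal (-0.33 with all probes and -0.51 on the product description) and protein kinases (-0.53 with all probes). With the filter, outlier and trend settings all 22 lists kept direction and side of the threshold. Filters could not move them, since list genes are above background on all 4 arrays. Nor could the trend setting, as camera was run on the same values without the trend. The filter and trend settings therefore count among the 377 by construction. Over 104 named probes and 16 alternatives, 1467 of 1664 outcomes kept direction and side, 187 lost the call, 1 gained it and 9 reversed. Most losses came by the methods' t-test (71), without whole-male array 1 or 2 (26 and 28), and with no filter or spike-in scaling (19 each). The reversals, none past the threshold, were Smp_169560 at -0.14 with spike-in scaling (Q2_P37282) and -0.12 with no scaling, Smp_010660, the ribosomal protein L6 (Q2_P02540), at -0.014 with spike-in scaling, Smp_031710 (Q2_P27797) at -0.33 and -0.31, Smp_072350 (Q2_P20106), not called as reported, at -0.64 and -0.62, and Smp_043670 (Q2_P24508) at -0.27 and -0.24. The replicate block gave 2108 higher and 3006 lower. Same-numbered arrays deviated with a correlation of -0.06 over 2 pairs, so the numbers were not taken to pair samples; the block changed no list call and ended 4 of the 104 named calls. Not run were normexp on the mean signal, a column not used here, probes of S. mansoni only, since species is not marked in the files used, and the authors' normalized values per array, since the table holds group means. Signal over background limits the tests: 46.4% to 56.6% of spots per array lay well above it.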

Other observations

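The matched-list test of secretory genes was set before its result was seen, and the other tests here were chosen after. Among lists that were not called, glycosyltransferases, which add sugars to proteins and lipids, had 19 of 35 members higher, 10 lower and 6 that did not pass (20 and 13 adjusted over the list alone), with a median of 0.62 (-0.39 with spike-in scaling; camera adjusted p = 0.0892). Of 20 camera alternatives 8 called it, among them spike-in scaling (adjusted p = 0.0375), all probes (0.0245) and the product description alone (0.0371). A beta-1,3-N-acetylglucosaminyltransferase (Smp_151220) rose by 4.44 and an N-acetylgalactosaminyltransferase (Smp_159490), of a family that starts O-linked chains on mucins, by 3.55, while a galactosyltransferase (Smp_102400) fell by 2.74. Transcription factors had 30 of 80 higher and 19 lower (median 0.35, -0.65 with spike-in scaling; adjusted p = 0.155), and protein kinases 32 of 89 higher and 26 lower (median 0.22, -0.79 with spike-in scaling; adjusted p = 0.42). Their largest increases, Smp_151160 and Smp_138570 (5.78), match by words in BLAST text and carry no such product description. The zinc finger factor gli2 (Smp_000530) fell by 2.44 and the checkpoint kinase chk2 (Smp_171370) by 3.52. Ribosomal proteins had 8 of 51 higher and 6 lower (median 0.31, -0.70 with spike-in scaling; adjusted p = 0.0684). Heat shock genes had 13 of 50 higher and 12 lower (median 0.17, -0.84 with spike-in scaling; adjusted p = 0.591), with an HSP70 homolog down by 3.59. Of 20 camera alternatives, 4 called transcription factors, 2 ribosomal proteins, and 0 protein kinases or heat shock genes. Under spike-in scaling 4 glycosyltransferases were higher and 13 lower, 6 and 25 transcription factors, and 2 and 32 protein kinases. Ribosomal proteins then had 0 higher and 10 lower, and heat shock genes 1 and 17.

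Male reproductive genes had 22 of 34 lower and 8 higher (median -1.04, adjusted p = 0.0735), with tektin (Smp_046410), of sperm tails, down by 2.96 and the mitotic checkpoint gene bub3 (Smp_045060) up by 2.45. Ion pumps and channels had 17 of 32 lower and 5 higher (median -0.74, adjusted p = 0.1), and a TRP-M channel (Smp_161640) rose by 3.17. Lysosomal and lipid hydrolases had 17 of 36 lower and 8 higher (median -0.58, adjusted p = 0.221), and a ceramidase (Smp_147460) rose by 3.26 at its brightest probe. Of the 3 probes of that ceramidase 2 were called higher, and the lowest stood at -0.41. Redox genes had 10 of 21 lower and 5 higher (median -0.58, adjusted p = 0.372): a superoxide dismutase (Smp_095980) rose by 5.85 at its brightest probe, while a probe with the same extracellular superoxide dismutase description but no genome prediction (Q2_P27243) fell by 3.04, so probes under 1 description disagreed. Neuronal genes had 18 of 48 higher and 21 lower (median 0.00 with a mean of 0.01, and -1.01 with spike-in scaling; adjusted p = 0.722). Fatty acid and lipid transport genes had 4 of 11 higher and 6 lower (median -0.90, adjusted p = 0.616), and protease inhibitors 4 of 9 higher and 3 lower (median -0.20, adjusted p = 0.903). Of 20 camera alternatives, 6 called male reproductive genes, 1 ion pumps and channels, and 0 the others of this paragraph. Under spike-in scaling 0 neuronal genes were higher and 23 lower, and 0 and 4 protease inhibitors.

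Eggshell, female-specific, Pro-His-rich and tyrosinase transcripts were higher in the male gland, and Smp_131110 was among the brightest, with a mean signal of 123402 against 6835 in whole males. The 4 members with no eggshell description rose too, the lowest by 4.69 ± 0.15 (SE). They belong to the 9 set apart after their values were seen, so this does not decide on cross-hybridisation among repetitive eggshell probes. Under spike-in scaling, which shifts every probe alike, the lowest of the 9 still stood at 3.69 ± 0.58. RNA of vitelline cells from paired females may be the source, or expression in the gland. That 9 of 9 such members rose decides nothing, as they were set apart after their values were seen, and no female sample was analysed here, so these cannot be told apart. Of the list's 21 members, 3 also stand in another list, all were selected by the authors on these samples, and 7 of its other 12 members, such as apoferritin-2, fell. Those falls leave female RNA open, since other tissues can express members such as the fructose bisphosphate aldolase (Smp_042160). Comparison with virgin males, or in situ hybridisation of Smp_131110 to the gland, would test the source.

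Secretory pathway genes were called higher by camera, with a median of 0.74, but not with an estimated correlation (adjusted p = 0.507). Under spike-in scaling camera still called the list higher (adjusted p = 0.000193), while its median was -0.26, with 2 members higher and 8 lower, since the bulk of genes moved down with it. A trend with signal strength was argued against, since the median lay at percentile 100 of 10000 random lists matched on mean signal, which ran from -0.71 to 0.55. Whether RNA of other secreting cells contributes was not tested, and a larger share of secretory machinery in gland cells could remain as a hypothesis that isolated gland cells would test.

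Nearly all calls were lower in the gland when arrays were scaled to spike-in probes. The 75th percentile over the spike-in level differed by -1.0 ± 0.51 (log2, SE) between the groups, and the share of signal in the 100 brightest spots predicts -0.25. A shift of -0.75 ± 0.44 was left, so a few abundant transcripts may account for part of it. It cannot be told apart from a difference in RNA input or labelling, as the spike-in level itself differed by 0.78 between the gland arrays.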
